A study of Homo sapiens with 10 samples.

How the data were processed

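RNA was sequenced from 10 libraries of CWR22-Rv1 cells (22Rv1), an established human prostate cancer cell line. Per the labels' protocols, the cells had been transfected with 20 nM small interfering RNA (siRNA) for 3 days. One count table held 3 libraries with a non-targeting siRNA (siNTC) and 3 with an siRNA against SETD7. The other held 2 siNTC libraries, which the labels name as the controls for this knockdown, and 2 libraries with an siRNA against MLL1, the older name of KMT2A. Every column name of the MLL1 table carries the label Veh, and no column name of the SETD7 table does. The control columns of the MLL1 table are named siNC and siNTC. The sources used here do not explain Veh or say whether these control names mark different siRNAs. The labels' growth protocol gives a serum-supplemented medium, whereas the series description speaks of hormone-depleted conditions, and the sources used here do not say how these fit together. The library kit is described in the labels' protocols both as a stranded total RNA kit and as an mRNA kit. The siRNA sequences were not given in the sources used here.

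The deposited values were raw counts per gene, whole numbers that the authors had not normalised, per the file headers. Per the submitters' processing notes, the tools were FastQC 0.11.9, STAR 2.7.2 and featureCounts 2.0.1 on the hg19/GRCh37 build. The strand setting of the counting, the treatment of reads that fit several genes and the annotation release were not given in the sources used here. The table layout was that of featureCounts, with the exon coordinates and the summed exon length of each gene. Reads from overlapping exons, antisense partners included, could not be assigned with certainty, so the share of a gene's exon length that overlaps other genes was computed from the deposited coordinates for every gene named.

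Both tables listed the same 63677 Ensembl gene IDs. Symbols were found for 40044 of them, a GENCODE 29 gene type for 52526, and 29033 genes had no count in any library. Gene positions were taken from the deposited coordinates. GENCODE 29 was otherwise used only for gene types and transcript sequences, matched by gene ID.

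Total counts per library lay between 12070548 and 14294147 in the siSETD7 table and between 4831606 and 6836714 in the siMLL1 table. A count of 0 allows up to 3 counts, which is 0.21 to 0.249 CPM (counts scaled by library size) in the first table and 0.439 to 0.621 CPM in the second. Such floors, and the intervals given for shares, cover counting error only. The composition differed between the tables: 97.5% of counts fell in protein-coding genes in the siSETD7 table, against 89.6 to 91.6% in the siMLL1 table, and the noncoding 7SK RNA took 1.98 to 2.3% of the counts in the latter.

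Each knockdown was compared with the siNTC libraries of its own table. Genes were kept by filterByExpr, libraries were scaled by TMM factors, and genes were tested with the robust quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all genes tested. A gene with an adjusted p below 0.05 was called, and rose, fell and changed are used for called genes. Standard errors of fitted log2 changes came from the same model. CPM values are given as mean and standard deviation (SD) of the libraries of a group. A difference between the knockdowns was tested in 1 fit over all 10 libraries as the siSETD7 effect minus the siMLL1 effect. The fold changes of the knockdowns were also compared by their correlation across genes and by the overlap of calls with Fisher's exact test.

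The siMLL1 table carried the numbers 2 and 4 in its column names, while the titles carry 1 and 2. Its libraries separated by the column number: the deviations of knockdown and control libraries with the same number correlated at 0.798 across 14185 genes. The test planned for this knockdown had no term for the number. A fit with the column number as a batch term, which leaves 1 residual degree of freedom, was added after the data were seen, and both are reported. Log2 ratios within each number used CPM plus 0.5.

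A collection of 34 gene lists (hormone response, lineage markers, cell cycle, stress, metabolism, chromatin complexes and RNA quality) was written from textbook knowledge, and 31 of them had at least 5 tested members in each knockdown. Lists were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with a correlation estimated from the data and fry were run beside it. With an estimated correlation, camera takes its degrees of freedom from the libraries, which were few, so its p can rise whatever the correlation. The p of fry tests whether the genes of a list move on balance one way and its mixed p whether they change in either direction, and neither compares a list with other genes. The number of members called was also counted with p-values adjusted over the list alone.

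The designs, the lists, the alternatives and the rule for naming genes were written before the data were examined. The rule took the targeted gene and the 10 largest rises and 10 largest falls among called genes. Those had to have a symbol, a protein-coding type where one was known, a mean log2 CPM of at least 1, and all knockdown libraries on 1 side of all controls (for the batch fit, added later, each knockdown library on the same side of the control with its column number). It also took a panel of genes of androgen signalling, proliferation and the targets themselves (KLK3, KLK2, TMPRSS2, FKBP5, FOXA1, UBE2C, MYC, SETD7 and KMT2A). A few further genes and 1 list are not reported here. For each list past the threshold, and for both androgen lists, it took up to 4 called members with the smallest adjusted p, or the 2 most expressed members if fewer than 2 were called. For the difference of the knockdowns it took the 5 largest called differences each way.

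Alternatives covered median-of-ratios size factors, no low-count filter, a filter of 1 CPM in every library of 1 group, DESeq2 1.42.0, the replicate number as a block, each library left out in turn, all 10 libraries in 1 fit, and an adjusted p below 0.01. Another alternative removed a smooth trend on GC content and gene length from the gene tests. Its use for lists and together with the batch term, and the removal of a GC or length trend alone, were added after the data were seen. For it, each library's log2 CPM (prior count 2) minus the mean of all libraries was fitted with a smooth function (basis size 8), weighted by mean CPM up to 100, in mgcv 1.9.3, and the fitted values entered the model as offsets. GC content was that of each gene's longest GENCODE 29 transcript. Every split of the 6 siSETD7-table libraries into groups of 3, 10 splits in all, was refitted. A scan of 7-base words in 3′ untranslated regions, with 1000 permutations, used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. It took 3′ untranslated regions of at least 50 bases, genes with a mean log2 CPM above 3, and words held by at least 100 genes. Fitted log2 changes were limited to 1.5 in either direction and freed of a polynomial trend on the length and GC content of the untranslated region before each word's z was computed.

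The scripts were tested on simulated data with the real genes' means and library sizes. For siSETD7 against siNTC, the quasi-likelihood test recovered 41.8% of genes changed 1.2-fold, 86.6% of those changed 1.5-fold and 98.5% of those changed 2-fold, and 14 of its 165 calls were unchanged genes among 15171 tested. DESeq2 recovered 31.3%, 76.1% and 97.0% of the same sizes, with 1 unchanged gene among 137 calls. With a simulated tilt on GC content, 3100 of 3287 calls were unchanged genes without the trend correction and 19 of 196 were with it. For siMLL1 without the batch term, 0% of genes changed 1.5-, 2- or 4-fold were recovered. With it, 37.3%, 80.6% and 98.5% were recovered at those sizes, with 7 unchanged genes among 151 calls over 14140 genes. DESeq2 with the batch term recovered 7.46%, 46.3% and 92.4%. It made 97 calls on these simulated counts, against 1 in the real data. The siMLL1 counts were drawn from means and spreads fitted with the batch term, so the gain from that term was built in. The word scan found 20 of 20 planted words, or a word that shared 6 bases with them, at a planted log2 change of -0.08, which is larger than the -0.0552 seen for the strongest real word. No column of per-sample values was left out. No other data type was analysed, and sequence reads were not realigned.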

Results

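Gene expression was measured by RNA sequencing in 22Rv1 prostate cancer cells after knockdown of either of 2 lysine methyltransferases. SETD7 methylates histone and non-histone proteins, and the series asks whether it acts as a repressor of transcription through the pioneer factor FOXA1. MLL1, the product of KMT2A, methylates histone H3 at active promoters. The siSETD7 experiment held 3 siNTC libraries of 13264065, 12747145 and 12070548 counts and 3 siSETD7 libraries of 12364557, 14286059 and 14294147. The siMLL1 experiment held 2 siNTC libraries of 4872598 and 6836714 counts and 2 siMLL1 libraries of 4831606 and 5910673, which carried the numbers 2 and 4. Replicates of the siSETD7 experiment correlated at 0.996 in log2 CPM, against 0.935 and 0.937 for the pairs of replicates in the siMLL1 experiment.

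Both targets were lower in every library that carried their siRNA. SETD7 (ENSG00000145391, GRCh37 chromosome 4, 140417095 to 140527853) had 2112, 2075 and 1937 counts with siNTC and 509, 534 and 579 with siSETD7. Its level went from 160 ± 1.98 CPM to 40.0 ± 2.07 CPM (SD, n = 3), a 4.02-fold fall with a log2 change of -2.01 (SE 0.051) and an adjusted p = 5.39e-39 by edgeR. KMT2A (ENSG00000118058, chromosome 11, 118307205 to 118397539) had 1078 counts in siNTC number 2 and 981 in number 4, against 394 and 358 with siMLL1. Its log2 ratio was -1.42 within number 2 and -1.23 within number 4, and its mean level was 184 ± 62.5 CPM with siNTC and 72.1 ± 18.3 CPM with siMLL1 (SD, n = 2). KMT2A had a log2 change of 0.13 with siSETD7 (adjusted p = 0.156), which was called without siNTC library 1 (0.19, adjusted p = 0.00215) and with no low-count filter (0.13, adjusted p = 0.0309). SETD7 had a log2 change of 0.09 with siMLL1 (SE 0.268), in a test that recovered 0% of simulated changes up to 4-fold.

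**Figure D1:**
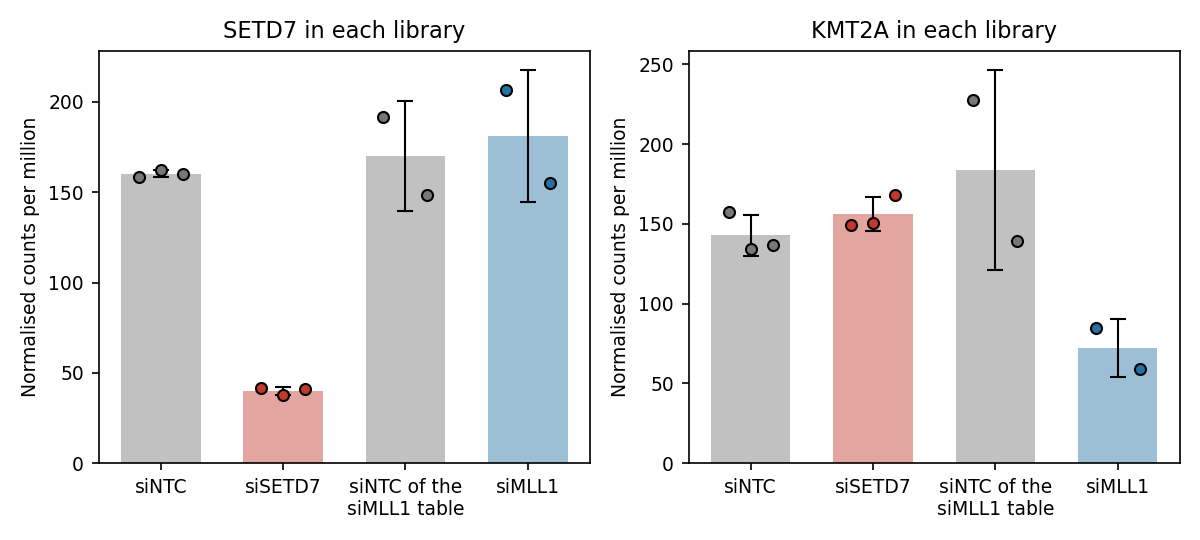
Levels in CPM of SETD7 and KMT2A in the 10 libraries, with a point per library, bars at the group mean and error bars of 1 SD. SETD7 stood at 160 CPM with siNTC and at 40.0 CPM with siSETD7, and KMT2A stood at 184 CPM with siNTC and at 72.1 CPM with siMLL1.

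Many genes differed by small amounts between the siSETD7 and siNTC libraries. Of 15356 genes tested (n = 3 per group), 3011 were called: 1770 rose and 1241 fell, so that 58.8% of the calls were higher. The median called change was 1.18-fold, the 10th and 90th percentiles were 1.10- and 1.37-fold, and 34 calls reached 2-fold. Protein-coding genes made up 2872 of the calls, of which 1689 rose. DESeq2 gave an adjusted p to 11565 genes and called 1838 of them, 1814 shared with the edgeR test. The edgeR test called 1950 genes without siNTC library 3 (668 lower) and 771 lower genes without siSETD7 library 3. When all 10 libraries shared a single spread, 1 gene, SETD7, was called. After a trend on GC content and gene length was removed, 1215 genes were called (597 higher, 618 lower), 771 of them among the calls made before. Of 2975 earlier calls with a GC value 2204 were lost, and for these a library bias could not be told from a response. The 2-fold calls numbered 1 by DESeq2, 10 after trend removal, 11 at an adjusted p below 0.01 and 54 without siSETD7 library 2.

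The largest rise was that of FMO1 (ENSG00000010932, chromosome 1, 171217638 to 171255117), a flavin-containing monooxygenase that oxidises xenobiotics. It went from 1.31 ± 0.257 to 3.33 ± 1.10 CPM (SD, n = 3), a log2 change of 1.35 (SE 0.265, adjusted p = 0.000102). FMO1 rested on 14 to 65 counts per library and was not a 2-fold call of DESeq2, which made that call for SETD7 alone. TMED7, a cargo receptor of the early secretory pathway, rose by 0.94 on the log2 scale, ALG10, a glucosyltransferase of N-glycan assembly, by 0.88, and EID1, an inhibitor of the acetyltransferase EP300, by 0.93. UGT2B15, which inactivates androgens by glucuronidation, rose by 0.87, FST, the activin-binding protein follistatin, by 0.82, and IPMK, an inositol phosphate kinase, by 0.75. CIBAR1 (0.99), ZNF8-ERVK3-1 (0.86) and FAM241A (0.75) completed the 10 largest rises. Exons of other genes overlapped 65.4% of the exon length of ZNF8-ERVK3-1, 53.3% of ALG10, 30.1% of EID1, 29.8% of CIBAR1 and 24.3% of TMED7, so their counts may hold reads of neighbours. The call for EID1 was lost without siSETD7 library 3 (adjusted p = 0.0524), and that for ZNF8-ERVK3-1 without siNTC library 2 (0.118), siSETD7 library 1 (0.0706) or siSETD7 library 3 (0.0533). After the GC and length trend was removed IPMK stood at 0.49.

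After SETD7 itself, the largest falls were those of ADAT3, a subunit of the tRNA adenosine deaminase (log2 change -1.15), GALR2, a galanin receptor (-1.15, SE 0.245), and GMPR, the GMP reductase of purine salvage (-1.03). GALR2 (ENSG00000182687, chromosome 17, 74070875 to 74073622) went from 3.51 ± 0.897 to 1.56 ± 0.293 CPM (SD, n = 3, adjusted p = 0.000353). Counts per library were 20 to 63 for ADAT3, 15 to 55 for GALR2 and 13 to 39 for GMPR. None of these genes was a 2-fold call of DESeq2. C4orf48 (-0.87), TGFBR3L (-0.84), ZNF296 (-0.82), AMZ1 (-0.79), ACTL10 (-0.78) and the brush-border myosin MYO1A (-0.77) followed. ADAT3 shared 35.3% of its exon length with SCAMP4, and TGFBR3L 17.7% with an overlapping gene. TGFBR3L was not called without siNTC library 2 (adjusted p = 0.116) or siSETD7 library 1 (0.0987). ACTL10 was not called without siNTC library 2 (0.0674), siNTC library 3 (0.205), siSETD7 library 2 (0.0576) or siSETD7 library 3 (0.191), nor after the GC and length trend was removed (-0.55, adjusted p = 0.223). Trend removal also moved C4orf48 to -0.50, TGFBR3L to -0.46 and ZNF296 to -0.54, which stayed called.

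Among the androgen-signalling genes of the panel, the kallikreins KLK3, which encodes prostate-specific antigen, and KLK2 each fell by 0.24 on the log2 scale (adjusted p = 0.000307 and 0.000656). KLK3 went from 79.1 ± 2.06 to 66.8 ± 1.91 CPM (SD, n = 3). MYC fell by 0.12 (adjusted p = 0.0117), a call that ended without siSETD7 library 3 (adjusted p = 0.123) and after trend removal (-0.07, adjusted p = 0.152). Not called were FOXA1 (0.01, adjusted p = 0.880), FKBP5 (0.05, 0.431), TMPRSS2 (-0.30, 0.0795) and the mitotic ubiquitin-conjugating enzyme gene UBE2C (-0.11, 0.106). Leaving out siNTC library 2 called TMPRSS2 (-0.39, adjusted p = 0.0343), and leaving out siNTC library 1 or siSETD7 library 2 called UBE2C (adjusted p = 0.0353 and 0.0473).

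Genes of sterol synthesis fell together with siSETD7. In the cholesterol synthesis and uptake list, 17 of 25 members fell, 1 rose (SC5D) and 7 did not pass the test (18 lower and 1 higher adjusted over the list alone), with a median log2 change of -0.21 and a camera adjusted p = 4.60e-09. The list was not called with an estimated correlation (p = 0.0225, adjusted p = 0.350). DHCR7, which makes the last double-bond reduction of the pathway, fell by 0.31, the squalene synthase FDFT1 by 0.24, and the demethylase CYP51A1 by 0.47. The exons of CYP51A1 overlapped other genes over 82.2% of their length. In the fatty acid synthesis list, 7 of 15 members fell and 1 rose (7 and 1 adjusted over the list alone, median -0.11, camera adjusted p = 8.77e-05). It was not called with an estimated correlation either (p = 0.0338, adjusted p = 0.350). The members that fell included the lipogenic transcription factors SREBF1 (-0.42) and MLXIPL (-0.40), the desaturase FADS2 (-0.27) and the ATP citrate lyase ACLY (-0.11). MLXIPL stood at -0.24 after trend removal.

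The list of hypoxia-response genes went up: 13 of 30 members rose, 1 fell and 16 did not pass (17 higher and 2 lower adjusted over the list alone), with a median log2 change of 0.17 and a camera adjusted p = 8.77e-05. The list was not called with an estimated correlation (adjusted p = 0.418) or by fry (adjusted p = 0.0732). The glycolytic genes LDHA (0.25) and PGK1 (0.20) and the endoplasmic reticulum oxidase ERO1A (0.33) rose, whereas the glucose transporter gene SLC2A1 fell (-0.18). In the list of unfolded-protein and ATF4 targets, 10 of 26 members fell and 2 rose (11 and 4 adjusted over the list alone, median -0.09, camera adjusted p = 0.00136). These targets had an adjusted p = 0.350 with an estimated correlation. Chaperones and folding enzymes such as HSPA5 (-0.18), PDIA4 (-0.27) and CRELD2 (-0.31) fell, while the cystine transporter gene SLC7A11 rose (0.40). After trend removal SLC7A11 was not called (0.14, adjusted p = 0.0579), and PGK1 and ERO1A stood at 0.13 and 0.15.

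**Figure D2:**
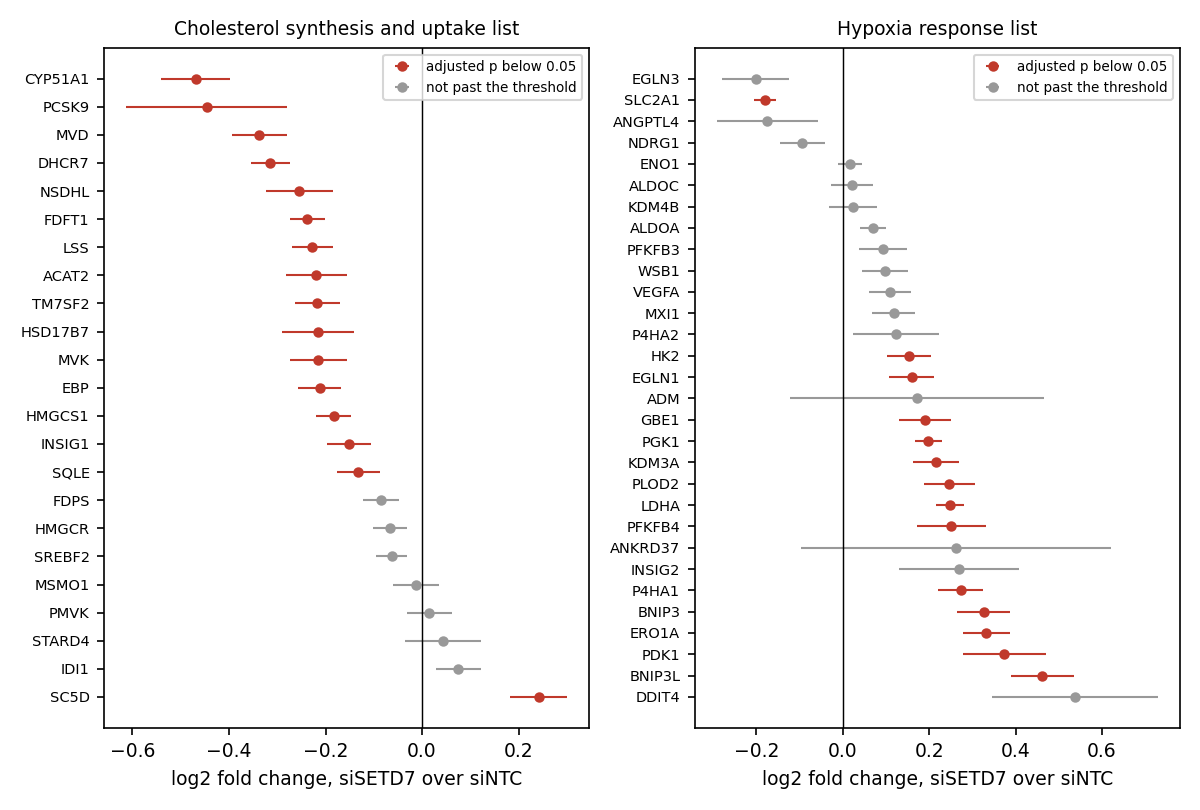
Fitted log2 change of members of the cholesterol synthesis and uptake and hypoxia-response lists (not every member is shown), siSETD7 against siNTC (n = 3 per group), with error bars of 1 SE and called members in red. In the cholesterol synthesis list 17 of 25 members fell, and in the hypoxia-response list 13 of 30 rose.

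Androgen-induced genes moved both ways: 5 of 38 rose and 8 fell (5 and 9 adjusted over the list alone), with a median of -0.02 and a camera adjusted p = 0.364. Among them the transcription factor gene ZBTB10 (0.31) and TPD52 (0.45) rose, while KLK4 (-0.19) fell. Of 25 androgen-repressed genes, 3 rose and 5 fell (3 and 6 adjusted over the list alone, median -0.09, adjusted p = 0.113). UGT2B15 and KLHL13 (0.43) rose, and the N-cadherin gene CDH2 (-0.41) and MYC fell. KLHL13 was not called without any 1 of siNTC library 2 or 3 or siSETD7 library 1 or 3 (adjusted p = 0.0507 to 0.101) or by DESeq2 (0.112). After trend removal both androgen lists were called lower (medians -0.07 and -0.11, camera adjusted p = 0.0125 and 0.00374). Camera with an estimated correlation gave each an adjusted p = 0.505 before trend removal and was not run after it. With the trend removed ZBTB10 and TPD52 stood at 0.15 and 0.23, and KLK4 (-0.06, adjusted p = 0.238) and KLHL13 (0.20, 0.400) were no longer called.

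No other list passed the camera threshold in the siSETD7 comparison. S phase genes held 5 rises and 3 falls among 49 (adjusted p = 0.492), and cytosolic ribosomal protein genes 4 rises and 2 falls among 53. Luminal epithelial markers held 2 rises and 5 falls among 19 (adjusted p = 0.105), and 0 of 5 stromal markers were called. By fry, 7 lists moved on balance in 1 direction, against 3 without siNTC library 3, siSETD7 library 1 or siSETD7 library 2 and 0 with the replicate block. Camera called 8 lists without siNTC library 1 and 10 lists after trend removal.

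The fold changes with siSETD7 followed GC content. Across 14997 genes with a known sequence, Spearman's rho between fold change and GC content was -0.595, and it was -0.736 for the 10528 genes with a mean log2 CPM above 3. Genes are not independent replicates, so no p is given. Among these 10528 more expressed genes, the median log2 change went from 0.25 in genes of up to 36% GC to -0.27 in genes above 66%. In the same genes every siNTC library had a positive slope of log2 CPM on GC content relative to the mean library (0.0568, 0.0489 and 0.0966 per 10 points of GC). Every siSETD7 library had a negative one (-0.0534, -0.0446 and -0.104).

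**Figure D3:**
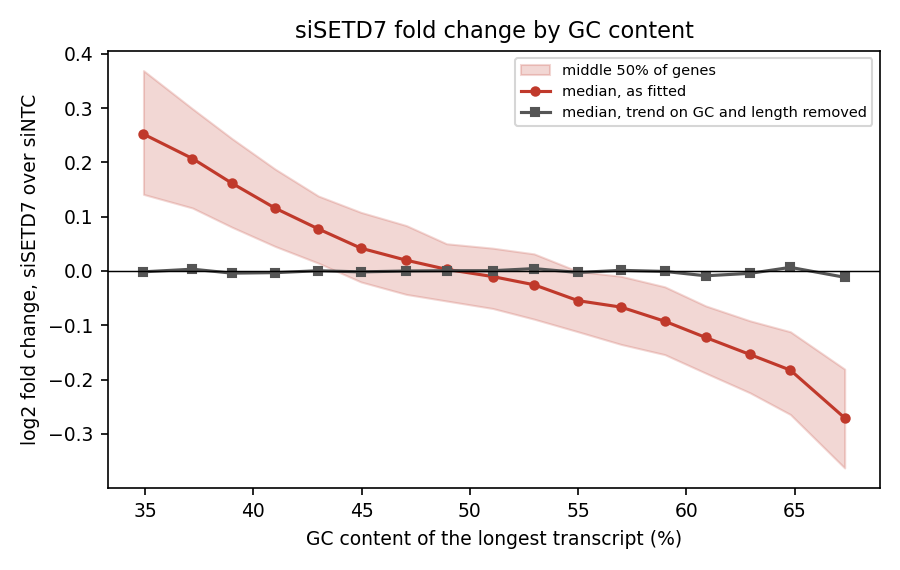
Median log2 change with siSETD7 by GC content of the longest transcript (percent), in the 10528 genes with a mean log2 CPM above 3. A band marks the middle 50% of genes and a second line the values after removal of the GC and length trend. The median lay at 0.25 in the lowest bin and at -0.27 in the highest.

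In the siMLL1 experiment the column number separated libraries more than the knockdown did. The edgeR test planned for it called 0 of 14355 genes (n = 2 per group), with 20 genes at an unadjusted p below 0.05, and DESeq2 called 0, with 8 at an unadjusted p below 0.05. KMT2A had a log2 change of -1.35 (SE 0.354) and an adjusted p = 1.00 (unadjusted p = 0.0128 by edgeR). With the column number as a batch term, a fit added after the data were seen, edgeR called 55 genes, of which 9 rose, 46 fell and 14 reached 2-fold, with 1044 genes at an unadjusted p below 0.05. The median called change was 1.72-fold. KMT2A then fell by 1.33 on the log2 scale (SE 0.151, adjusted p = 6.41e-09), and DESeq2 with the same term called KMT2A alone. The batch fit called 21 genes at an adjusted p below 0.01, 90 with RLE size factors, 110 with the 1 CPM filter, 188 with all 10 libraries in 1 fit with blocks and 225 after trend removal.

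The genes that fell most with siMLL1, all from the fit with the batch term, were ARL9, an ARF-like GTPase gene (-2.24), and CYP1A2, a xenobiotic cytochrome P450 (-2.01). CYP1A2 (ENSG00000140505, chromosome 15, 75041185 to 75048543) stood at 13.7 ± 1.74 CPM with siNTC and 3.36 ± 1.09 CPM with siMLL1 (SD, n = 2, adjusted p = 5.44e-05). Next came the neuronal genes HPCAL4 (-1.82) and ATCAY (-1.73), then SKIDA1 (-1.59), the kinesin gene KIF26A (-1.47), the cadherin gene CDH23 (-1.37, 20.2% of its exon length shared), FAM43A (-1.34) and TMEM45A (-1.33). The lowest count in any library was 2 for HPCAL4, 4 for ATCAY, 8 for CDH23, 9 for KIF26A and 11 for SKIDA1. ARL9 rested on 3 to 20 counts per library. It was not called with no low-count filter (adjusted p = 0.0537), with all 10 libraries in 1 fit with blocks (0.0552) or when only genes with a GC value were tested (0.0617). The last setting also ended the calls of TMEM45A (0.0629), H2BC11 (0.0619), CENPE (0.0617) and SFT2D2 (0.0573). H2BC11, CENPE, KIF26A, CDH23, FAM43A, HPCAL4 and ATCAY separated from siNTC only within each number. IGFBP3, an insulin-like growth factor binding protein, rose most (0.80), from 63.7 ± 12.1 to 110 ± 15.2 CPM (SD, n = 2, adjusted p = 0.00347). LRRC8A, a volume-regulated anion channel subunit (0.73), HSPA2 (0.68), the histone gene H2BC11 (0.67), STARD10 (0.66, 19.5% shared), the glycine decarboxylase gene GLDC (0.65), the centromere motor gene CENPE (0.61), SFT2D2 (0.60) and STK40 (0.60) also rose. Of the panel genes named here, none but KMT2A was called, and that only in the fit with the batch term, with log2 changes in the batch fit of -0.08 for KLK3, -0.07 for KLK2, -0.19 for TMPRSS2, -0.05 for FKBP5, -0.16 for FOXA1, 0.10 for UBE2C and 0.04 for MYC.

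**Figure D4:**
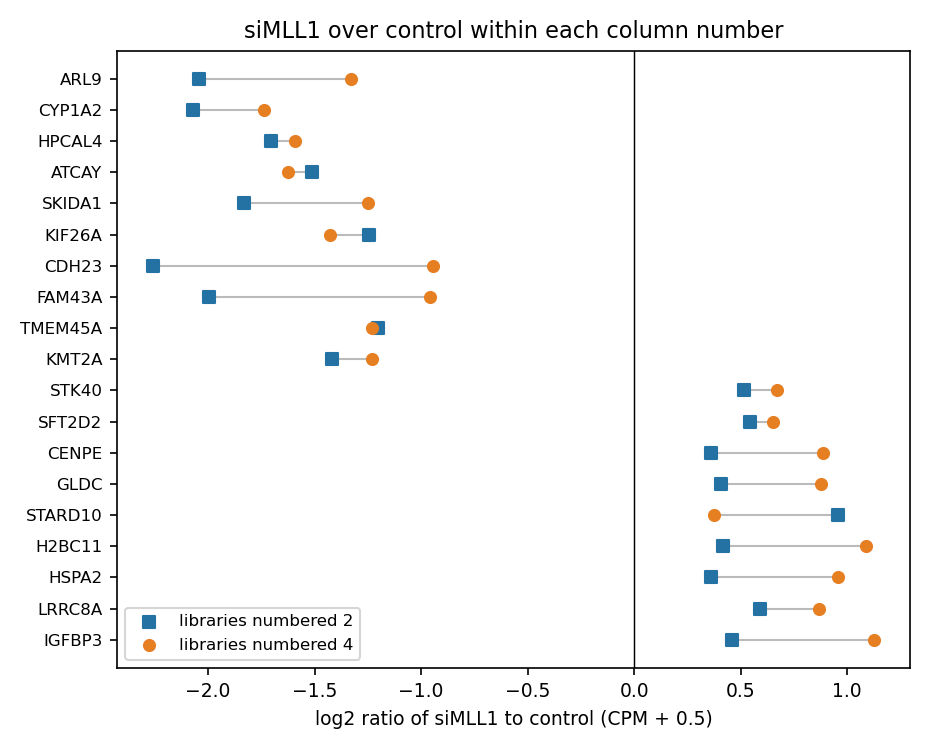
Log2 ratio of siMLL1 to siNTC (CPM plus 0.5) within column numbers 2 and 4, a point per number, for the genes with the largest called rises and falls in the fit with the batch term. KMT2A lay at -1.42 and -1.23. Every gene shown lay on the same side of 0 in both numbers, which the rule for naming genes required.

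Without the batch term camera with a preset correlation called 10 of 31 lists with siMLL1, although no member of any list was called. Each of these lists had an adjusted p = 0.788 with an estimated correlation, and fry called 0 lists. Leaving out 1 library reversed the camera direction of the S phase, G2/M, ribosome biogenesis, hypoxia-response, p53 target and HOXA and MEIS lists. It also turned the median of oxidative phosphorylation genes negative. G2/M genes had a median log2 change of 0.19 (camera adjusted p = 6.10e-05), S phase genes 0.18 (0.00319), oxidative phosphorylation genes 0.10 (0.00137) and ribosome biogenesis genes 0.08 (0.00388). Hypoxia-response genes had a median of -0.30 (6.10e-05), genes of the HOXB, HOXC and HOXD clusters -0.29 (0.000104), mesenchymal markers -0.46 (0.000677), Wnt targets -0.13 (0.0243), HOXA and MEIS genes -0.33 (0.0271) and p53 targets -0.16 (0.0492). Camera called 18 lists without siNTC number 2, 19 without siMLL1 number 4, and 9 without siNTC number 4 or siMLL1 number 2. Only the HOXB, HOXC and HOXD genes without siNTC number 4, and hypoxia-response genes and p53 targets without siMLL1 number 2, kept both call and direction in the last settings. Without siNTC number 4 and siMLL1 number 2 in turn, the calls were lost for mesenchymal markers (adjusted p = 0.0906 and 0.276), Wnt targets (0.264 and 0.739), HOXA and MEIS genes (0.661 and 0.868) and oxidative phosphorylation genes (0.965 and 0.597). Calls were also lost without siNTC number 4 for p53 targets (0.981) and hypoxia-response genes (0.0988), and without siMLL1 number 2 for the HOXB, HOXC and HOXD and the ribosome biogenesis genes (0.0846 each). The filter of 1 CPM in every library of 1 group ended those of p53 targets and of HOXA and MEIS genes (0.0913 each), leaving out siMLL1 number 4 that of p53 targets (0.506), and trend removal that of oxidative phosphorylation genes (0.0509). Leaving out siNTC number 4 turned the median of S phase genes to -0.37, of G2/M genes to -0.26 and of ribosome biogenesis genes to -0.26. It turned that of hypoxia-response genes to 0.14 and of oxidative phosphorylation genes to -0.04. Leaving out siMLL1 number 2 turned the S phase, G2/M, ribosome biogenesis and oxidative phosphorylation medians to -0.74, -0.35, -0.18 and -0.01.

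With the batch term the same 10 lists and 8 more were called, each with an adjusted p of 0.619 with an estimated correlation. Of 54 G2/M genes, 1 rose and 0 fell (2 and 0 adjusted over the list alone, median 0.21, camera adjusted p = 1.62e-12). The member that rose was CENPE, and the expressed members CENPF (0.32) and NCAPD2 (-0.14) were not called. Among 49 S phase genes none was called (3 higher adjusted over the list alone, median 0.18, adjusted p = 3.52e-10), with 0.29 for MCM7 and 0.18 for MCM4. Of 16 replication-dependent histone genes, 1 rose (4 adjusted over the list alone, median 0.26, adjusted p = 6.83e-10). The medians within numbers 2 and 4 were 0.12 and 0.32 for G2/M genes, 0.16 and 0.21 for S phase genes and 0.13 and 0.39 for the histone genes.

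Among 29 hypoxia-response genes, NDRG1 (-0.66) and the mitophagy receptor gene BNIP3L (-0.64) fell and none rose in that fit (5 lower and 1 higher adjusted over the list alone, median -0.26, adjusted p = 5.45e-10). The list's median was 0.04 within number 2 and -0.56 within number 4, so its direction was that of number 4. Of 10 mesenchymal markers the fibronectin gene FN1 fell (-0.77), with 3 lower adjusted over the list alone (median -0.43, adjusted p = 3.43e-05, -0.52 and -0.30 within numbers). Of 17 genes of the HOXB, HOXC and HOXD clusters HOXB13, a prostate lineage factor, fell (-0.90), with 1 lower adjusted over the list alone (median -0.29, adjusted p = 0.000428). HOXB13 had log2 ratios of -1.43 and -0.40 within numbers 2 and 4 and shared 20.0% of its exon length with PRAC2. It was not called with all 10 libraries in 1 fit with blocks (-0.87, adjusted p = 0.0905). Of 15 genes with short-lived transcripts ATF3 (-0.93) and JUN (-0.78) fell (3 lower adjusted over the list alone, median -0.24, adjusted p = 0.000428), and JUN was not called when only genes with a GC value were tested (adjusted p = 0.0573). BNIP3L, ATF3 and JUN separated from siNTC only within each number.

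The other lists called in the batch fit held at most 1 called member each. Ribosome biogenesis genes (median 0.15, 0 of 39 called) and oxidative phosphorylation genes (0.11, 0 of 34) were higher as lists. Unfolded-protein and ATF4 targets (-0.11, 1 of 26 fell), Wnt targets (-0.13, 0 of 14), nuclear noncoding RNAs (-0.15, 1 of 7 fell), p53 targets (-0.17, 0 of 35), interferon-response genes (-0.13, 0 of 22), basal epithelial markers (-0.35, 0 of 7) and HOXA and MEIS genes (-0.33, 0 of 6) were lower. In the MLL complex list (-0.07, adjusted p = 0.0478) the 1 gene of 23 that fell was KMT2A itself, and the list was not called when only genes with a GC value were tested (0.0527) or after trend removal (-0.02, 0.105). Trend removal also ended the calls of basal epithelial markers (adjusted p = 0.0626) and nuclear noncoding RNAs (0.0816) and moved the median of oxidative phosphorylation genes to 0.04, and the 1 CPM filter ended the call of HOXA and MEIS genes (0.0528). Neither androgen list was called: the induced genes had a median of 0.00 and 1 fall among 39, and the repressed genes a median of -0.04 and 0 calls among 23.

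The effects of the knockdowns were compared directly, although knockdown and experiment differ together, so that a difference belongs to the experiments' contrasts. Of 17401 genes tested, edgeR called 1, SETD7, with a difference of -2.11 (adjusted p = 0.0273), and 792 had an unadjusted p below 0.05. That call was lost without any 1 of the siNTC or siSETD7 libraries of the siSETD7 table (adjusted p = 0.205 to 0.325). The difference itself then stayed at -2.14 to -2.08. The call was also lost without siMLL1 number 2, where the difference was -1.90. DESeq2 called 40 genes, and 251 were called with terms for replicate and column number.

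Fold changes of the knockdowns hardly correlated: Pearson's r was 0.052 and Spearman's rho 0.055 across 13879 genes, which are not independent replicates. The siMLL1 log2 ratios within numbers 2 and 4 themselves correlated at only 0.147. A low r therefore does not show that the knockdowns act on different genes. Between the knockdowns r was -0.106 without siMLL1 number 2, -0.0452 without siNTC number 4 and 0.194 without siMLL1 number 4. Overlaps of calls were tested in 4 combinations, using the siMLL1 calls of the batch fit and leaving out SETD7 and KMT2A. The test treats genes as independent and equally easy to call, which they are not, so its p-values are a rough guide. GLDC, HSPA2, LRRC8A, STARD10 and STK40 fell with siSETD7 and rose with siMLL1, 5 genes against 0.703 for independent lists. The two-sided Fisher's exact p was 0.000233, and 0.000930 after Benjamini-Hochberg adjustment over the 4 combinations. DESeq2 with the batch term called none of these 5 genes with siMLL1. The siSETD7 calls used were those made before the GC and length trend was removed. Its removal ended 2204 of the 2975 siSETD7 calls with a GC value, and the overlap was not tested after it. BNIP3L, CDKN1B, HGF and HINT3 went the opposite way, 4 genes against 5.64 (exact p = 0.651). For calls in the same direction, 6 genes (ASS1, GPX4, NIBAN1, SEC61A1, SPOCK2 and 1 without a symbol) fell in both against 3.96 (exact p = 0.285), and 0 rose in both against 1.00 (exact p = 0.607).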

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

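The 3 tests on a short sequence word in 3' UTRs were written before their values were seen, and the remaining tests on GC content, sterol genes and called falls were chosen only after the result was seen. The first 9 values below were raised by a difference between the knockdowns. SETD7 differed by -2.11 on the log2 scale (adjusted p = 0.0273). Among lists, the hypoxia-response genes had a median difference of 0.47 (camera adjusted p = 1.91e-05), mesenchymal markers 0.33 (0.0479) and p53 targets 0.16 (0.0396). Cholesterol synthesis genes had a median of -0.25 (0.0297), oxidative phosphorylation genes -0.17 (0.000839), G2/M genes -0.16 (0.0297), ribosome biogenesis genes -0.11 (0.0426) and luminal epithelial markers -0.10 (0.0426). The adjusted p of these lists was 0.622 to 0.907 with an estimated correlation. Knockdown and experiment cannot be told apart in the differences of the lists. SETD7 itself fell by 2.01 within the siSETD7 table, against a log2 change of 0.09 with siMLL1.

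The first pattern is that fold changes with siSETD7 followed GC content. A library bias along the fitted GC and length trend, as the whole cause of the calls, is argued against by 771 genes. These were called before and after the trend was removed. A GC bias that the trend, based on each gene's longest transcript, does not capture could leave such calls. The gap of 0.0935 log2 units per 10 points of GC between the groups' slopes would arise from a library bias that followed the groups and equally from a response of GC-rich genes, so the calls that were lost may have either origin. Of 10 splits of the 6 libraries only 1, the real one, gave as many as 3011 calls, and the highest other split gave 0. The real split was again 1 of 10 after trend removal, with 1215 calls against 0 in the highest other. With 10 splits a share under 0.05 is impossible. Every other split mixed libraries of both groups, which dilutes any difference between them and widens the spread. The splits therefore cannot tell a response to the knockdown from a bias that followed the groups.

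The second pattern is that genes with the word TCCAATT in the 3' UTR were lower with siMLL1, with a z of -8.62 over 1016 of 10478 genes (permutation p = 0.000999, the smallest possible, among 15780 words). Base composition beyond GC content is argued against by a median z of -0.04 for the 209 words with the same bases in another order. A trend on the GC content of the untranslated regions had been removed before, which itself draws such a median towards 0. A match to the seed of an siRNA could produce the pattern: the word with the lowest z in number 2 had a z of -4.64 in number 4, and the mean change with the word in the 3' UTR differed by -0.0598 (SE 0.0109) from that with it in the coding sequence alone. As the cause of the called falls it is argued against, since 6 of 43 genes called lower, 14%, carried the word, against 9.7% of genes not called lower (Fisher's exact p = 0.303). The KMT2A transcript itself holds the word 3 times, but KMT2A was left out of the scan, so its own fall did not enter. The siRNA sequences were not given in the sources used here, so whether a seed match lies behind the small shift stays open.

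The third pattern is that sterol and fatty acid synthesis genes were lower with siSETD7. The GC and length trend is argued against as the cause, because the cholesterol list kept a camera adjusted p = 1.43e-15 after its removal. A growth state difference with the S phase fall seen between column numbers 4 and 2 is argued against by an S phase median of 0.0296, where scaling predicted -0.79. The test covered the S phase list alone. Of the 4 lists called with siSETD7, cholesterol synthesis, unfolded-protein and ATF4 and hypoxia-response genes moved the same way in number 4 against 2 (-0.42, -0.55 and 0.56). Fatty acid synthesis genes went the other way there (0.31, not called). Only 1 of 10 splits, the real one, moved the cholesterol median by as much as 0.21, against 0.06 in the highest other. The other splits mixed libraries of both groups, which shrinks any group difference, so they cannot tell a response from a culture difference. As many as 4 lists were called in 6 of 10 splits, with 6 in the highest other. A response of sterol regulation to loss of SETD7 and a culture difference that followed the groups may both remain, and with an estimated correlation the list had an adjusted p = 0.350, against camera values of 1.43e-15 to 4.60e-09 with and without the trend.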

How the results depend on the processing

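No test in this part was a new one, but the column number as a batch term, the removal of a GC trend alone, trend removal for lists or together with the batch term, all settings of the fit with the batch term, and all settings of the list tests on the difference of the knockdowns were chosen only after the result was seen. Among the results the report rests on, settings fixed at the start left 125 values the same, 26 weaker, 8 stronger and 3 moved. Settings added later left 61 the same, 25 weaker and 31 stronger. A count was taken as the same within a wide margin, such as 2104 against 3011 siSETD7 calls, or where it stayed at 0. Every count of siMLL1 calls under settings fixed at the start was such a 0, so its sameness says little. Of other values, 9 reversed under settings fixed at the start.

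For siSETD7, the fall of SETD7 kept its direction and call in every alternative. DESeq2 gave 1838 calls (1108 higher, 730 lower, 1 at 2-fold). With all 10 libraries in 1 fit there was 1 call (0 higher, 1 lower, 1 at 2-fold). The fitted spread between replicates was 17.7% there, against 3.43% in the siSETD7 table alone. With the length and GC trend removed there were 1215 calls (597 higher, 618 lower, 10 at 2-fold), with the replicate block as well 1157 (570 higher, 587 lower, 9 at 2-fold), and with the GC trend alone removed 1112 (539 higher, 573 lower, 8 at 2-fold). An adjusted p below 0.01 gave 1850 calls, 660 of them lower and 11 at 2-fold. Leaving out 1 library gave 1950 (without siNTC library 3) to 2847 calls, with 668 (without siNTC library 3) to 1289 lower and 25 to 54 at 2-fold (54 without siSETD7 library 2), and 771 lower without siSETD7 library 3. The replicate block gave 2864 calls, although deviations of libraries with the same number correlated at -0.000305, -0.0443 and -0.122, so the numbers did not pair libraries. The cause of these changes was not tested beyond the fewer libraries or stricter threshold of each setting.

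For siMLL1, every setting fixed at the start gave 0 calls. No paired analysis was possible on the numbers of the titles because the columns carry 2 and 4. The column number as a batch term gave 55 calls (9 higher, 46 lower, 14 at 2-fold) and KMT2A at -1.33, and the trend removed with that term gave 225 (43 higher, 182 lower, 46 at 2-fold) and KMT2A at -1.26. Starting from the fit with the batch term, no batch term gave 0 calls (0 higher, 0 lower, 0 at 2-fold) and KMT2A at -1.35. RLE size factors gave 90 calls (20 higher, 70 lower, 24 at 2-fold), and at least 1 CPM in every library of 1 group gave 110 (23 higher, 87 lower, 27 at 2-fold). DESeq2 gave 1 (0 higher, 1 lower, 1 at 2-fold), all 10 libraries in 1 fit with blocks 188 (65 higher, 123 lower), and an adjusted p below 0.01 gave 21 (2 higher, 19 lower). The cause was not tested. Leave-one-out was impossible for the fit with the batch term, which would keep 0 residual degrees of freedom. Without that term, a group left with a lone library was assumed to vary like the others.

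For the difference of the knockdowns there were 12 calls with no low-count filter, 40 by DESeq2, 251 with the siSETD7 replicate block and siMLL1 column number as a batch term, 0 at an adjusted p below 0.01, and 0 to 2 with 1 library left out (0 without any siNTC or siSETD7 library of the siSETD7 table or siMLL1 column 2, and 2 without siNTC column 4 or siMLL1 column 4). The correlation of fold changes went from -0.106 without siMLL1 column 2 to 0.194 without siMLL1 column 4, and was -0.0452 without siNTC column 4. The cause was not tested.

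The number of gene lists called was 0 with an estimated correlation in every comparison. For siSETD7 it was 10 with the trend removed, 10 with the replicate block as well, 10 with the GC trend alone removed, and 4 to 8 with 1 library left out (8 without siNTC library 1). For siMLL1 it was 18 with the batch term and 9 to 19 with 1 library left out, and the fit with the batch term called 14 with the trend removed and 17 with at least 1 CPM in every library of 1 group or when only genes with a GC value were tested. For the difference it was 5 with at least 1 CPM in every library of 1 group and 13 with the blocks. List medians with siMLL1 and 1 library left out ranged from -0.74 (without siMLL1 column 2) to 1.199 for S phase genes (also -0.37 without siNTC column 4), from -0.35 (without siMLL1 column 2) to 0.84 for G2/M genes (also -0.26 without siNTC column 4), and from -0.26 (without siNTC column 4) to 0.64 for ribosome biogenesis genes (also -0.18 without siMLL1 column 2). They ranged from -0.66 to 0.14 (without siNTC column 4) for hypoxia-response genes, from -0.96 to -0.0218 (without siNTC column 4) for HOXA and MEIS genes and from -0.17 to -0.00389 (without siNTC column 4) for p53 targets, where the camera direction reversed. Mesenchymal markers ranged from -0.83 to -0.21, Wnt targets from -0.60 to -0.04 and genes of the HOXB, HOXC and HOXD clusters from -0.63 to -0.27. Oxidative phosphorylation genes ranged from -0.04 to 0.24. The cause was not tested. At 4831606 to 6836714 counts per library in the siMLL1 experiment, the batch term took the share of simulated 2-fold changes recovered from 0% to 80.6%. The simulated counts came from means and spreads fitted with that term, so the gain was built in.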

Other observations

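All tests named in this part on the column numbers were chosen only after the result was seen. In the siMLL1 experiment, libraries numbered 4 differed from those numbered 2 in 5759 genes by edgeR (2931 higher, 2828 lower, 2216 at 2-fold) in the fit that also held the knockdown. Growth genes were lower in number 4. Each list named in this paragraph had an adjusted p = 0.520 by camera with an estimated correlation, and 0.0740 to 0.204 by fry. With 1 residual degree of freedom these tests could hardly pass any list, so they do not decide for or against the lists. Even the S phase list had an unadjusted p = 0.0609 by camera with an estimated correlation. Of 49 S phase genes 46 fell (median log2 difference -1.57), among them the replicative helicase genes MCM5 (-2.70), MCM2 (-2.39) and MCM4 (-2.07) and the origin licensing gene CDC6 (-2.25). All 16 replication-dependent histone genes fell (median -1.93), with H2BC11 at -3.32 and H1-5 at -2.85. Of 54 G2/M genes 52 fell (-1.05), including MKI67 (-1.90), CDC25A (-2.02) and CENPE (-1.80), and of 39 ribosome biogenesis genes 31 fell (-0.71), including UTP20 (-1.75) and NCL (-1.38). The unfolded-protein and ATF4 targets held 17 falls among 26 (-0.55), with MANF at -1.64 and HSPA5 at -1.56, and the cholesterol synthesis list 13 falls among 25 (-0.42), with ACAT2 at -1.69.

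Hypoxia and stromal genes were higher in number 4. Of 29 hypoxia-response genes 17 rose (median 0.56), including BNIP3L (1.54) and DDIT4 (1.91). Of 5 stromal markers 4 rose (2.19), with the collagen genes COL1A2 at 4.11, COL1A1 at 2.87 and COL3A1 at 2.19 and the smooth muscle gene TAGLN at 1.59. Of 7 basal epithelial markers 5 rose (1.11), including ITGB4 (2.90) and NGFR (2.84), and of 15 genes with short-lived transcripts 9 rose (0.91), including NR4A1 (2.03) and JUN (1.12). These lists had an adjusted p = 0.520 by camera with an estimated correlation, at the same 1 residual degree of freedom. Deviations from the group mean correlated at 0.798 between siNTC and siMLL1 libraries of the same number over 14185 genes, which are not independent replicates.

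Log2 ratios of siMLL1 to siNTC within number 2 and within number 4 correlated at 0.147 (Spearman's rho 0.095) over 14355 genes, which are likewise not independent. The 3' UTR scan for siSETD7 had its lowest z, -5.43, at ACGGATT (185 of 10076 genes, permutation p = 0.000999 among 15718 words). Genes with that word in the 3' UTR had a mean residual of -0.0442 (SE 0.0096), and the 290 genes with it in the coding sequence alone had -0.0159 (SE 0.0065). The SETD7 transcript of 7365 bases holds it 1 time, and its z with siMLL1 was 1.57. TCCAATT, the lowest word with siMLL1, had a z of 0.13 with siSETD7.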
